A study of Homo sapiens with 10 samples.

How the data were processed

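Poly(A) RNA of SH-SY5Y cells, a human neuroblastoma line grown in DMEM/F12 medium with serum, was sequenced 72 h after transfection with 100 nM of an siRNA against the long non-coding RNA LncND (3 libraries), a scrambled siRNA (3 libraries), 50 nM of a miR-143-3p mimic (2 libraries) or a scrambled miRNA (2 libraries). RNA was isolated with the MirVana kit and stranded mRNA libraries were made with the TruSeq kit, per the labels' protocols. The labels give replicate numbers and do not say that replicates were separate cultures, so the p-values measure the spread between these libraries, which may be technical. The 10 libraries were grouped by their labels, and all columns of measurements were assigned to a library.

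The values analysed were FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of a library), which the authors deposited in 1 table for the siRNA libraries and 1 for the miRNA libraries, with no other measurement score. TopHat, listed as version 1.0.0, Cufflinks and the hg19 build were named per the submitters' processing notes. The annotation, the strand setting of the quantification and the filter applied before deposit are not given in the sources used here. Each table had 25275 rows with 23609 gene names, of which 548 stood on several rows. Rows off the assembled chromosomes (1304) were left out, and 23585 genes were kept with 1 row each. Status words stood in the place of numbers in 274 rows of each table with too little data in every library, and in 18 rows of the siRNA table and 8 rows of the miRNA table where the quantification had failed. The lowest FPKM was 0.001, which stood in the place of 0. Because FPKM is scaled to the total of each library, a few abundant transcripts can lower all others, and FPKM of genes shorter than a fragment is unstable. In LncND siRNA replicate 1 the Y RNA gene RNY4 was listed at 1224670 FPKM, against the lowest value of 0.001 in the other 9 libraries, and the FPKM of that library summed to 1672810, against 423651 to 473263 in the others. Summed over genes of 300 bp or longer, this library's FPKM was 432908.

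No counts or library sizes were used here. Depth was estimated from the steps between the lowest FPKM values, scaled with 344 single-exon olfactory receptor genes whose transcript length is close to their locus length. The estimates, in M fragments, were 33.6, 28.2 and 32.0 for scrambled siRNA, 44.0, 28.4 and 25.6 for LncND siRNA, 27.2 and 13.8 for the mimic, and 14.4 and 37.6 for scrambled miRNA. At these depths a 2-kb transcript at 1 FPKM would be covered by 27.5 to 88.0 fragments. The estimates were not used in any test.

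FPKM values were tested as log2(FPKM + 1) with limma 3.58.1 (lmFit, then eBayes with a mean-variance trend) in R 4.3.3, each table alone, for genes with a mean of at least 1 FPKM over the libraries of the table. This left 12601 genes in the siRNA table and 12558 in the miRNA table, 12327 of them in both. Tests were 2-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05 on the adjusted p. Fold changes are on the log2(FPKM + 1) scale, which understates the change of genes with low FPKM. The difference of the 2 effects was tested in 1 limma fit of all 10 libraries, in which the offset between the tables cancels. The 2 comparisons share no control library. Overlaps of calls were tested with Fisher's exact test.

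The alternative settings, the tests and the rule for named genes were written before the data were examined, except the settings and tests named below as chosen later. For gene lists, 28 lists were also written before the data were examined. They covered Notch receptors, ligands and core machinery, Notch targets, neural progenitor, neuronal differentiation, synaptic and axon guidance genes, noradrenergic and mesenchymal neuroblastoma genes, G1/S and G2/M genes, p53 targets, apoptosis regulators, interferon, unfolded protein, heat shock, hypoxia and immediate early responses, cholesterol synthesis, glycolysis, reported miR-143 targets, RNA interference machinery, ribosomal proteins, genes near MYT1L at 2p25.3, reference genes, mitochondrially encoded genes, and markers of Schwann and glial, endothelial and blood, and epithelial cells. Lists with at least 5 tested members (24 in each comparison) were tested with camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists, and again with an estimated correlation and with fry. fry asks whether the members of a list move on balance in 1 direction and does not compare the list with other genes. Some genes stand in more than 1 list, such as CDKN1A among p53 targets and Notch targets and MYC among Notch targets and immediate early genes. The 13 mitochondrially encoded genes had no row in the tables. Of the markers of other cells, 3 of 20 Schwann and glial, 1 of 18 endothelial and blood and 2 of 18 epithelial genes were tested with LncND siRNA, and 3, 0 and 1 with the mimic.

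Named genes were those the study's title implies (NOTCH1 to NOTCH4, HES1 and HEY1), the 8 genes with the largest rise and the 8 with the largest fall per comparison among genes of at least 5 FPKM on average whose libraries did not overlap between groups, up to 4 members of a list by p, and up to 6 genes shared by or different between the comparisons. Results of some genes that met the rule are not reported here. No row carried the name LncND, so the knockdown itself was not analysed here.

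Matches to the miR-143-3p seed (bases 2 to 8) were counted in 3′ UTRs of the GENCODE 29 annotation of GRCh38, joined to the tables by gene name, so that no coordinates of the 2 builds were mixed. UTR sequences were found for 93.2% of the genes tested with siRNA and 93.6% with the mimic, and the others were left out. Genes with an 8mer match were compared with the other genes with a UTR by camera, and with UTR length and GC content as terms of a linear model. All 7-base words present in at least 100 UTRs were ranked by a rank-sum statistic, with and without removal of UTR length and GC content, with Python 3.11.15 and scipy 1.17.1.

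The procedures were tested on simulated data drawn from the means and spreads of the real genes. In 10 simulations of the siRNA comparison over 12601 genes, of which 200 were changed, limma called 91.3% of genes changed 1.25-fold, 99.6% at 1.5-fold, 99.8% at 2-fold and 0.0911% of unchanged genes. For the mimic comparison over 12558 genes these were 84.0%, 99.4%, 99.8% and 0.182%. Far more genes were called in the real data (66.9% with siRNA and 63.3% with the mimic), where the threshold on p is more lenient. These rates are therefore not the error rates of the real calls. The test of differences called 100% of genes changed 2-fold over 12327 genes. camera called 10 of 10 shifted lists of 30 genes in each comparison, and 1 of 10 unshifted lists in the siRNA comparison with the preset correlation. Noise was drawn for each gene alone, so this cannot show the error rate of camera for lists whose genes vary together. In the real data the estimated correlation with LncND siRNA was 0.716 for G2/M genes and 0.284 for p53 targets. A simulated effect of -0.15 on genes with a seed match was recovered at -0.152 over 11739 genes with siRNA and -0.151 over 11756 genes with the mimic, with the match ranked 1 in each of 20 simulations.

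Alternatives were pseudocounts of 0.1 and 0.5, no filter on low values or a mean of at least 5 FPKM, median-ratio scaling, quantile normalization, limma without the trend or with a robust prior, the replicate number as a block, a fold change of at least 1.5, leaving out each library in turn, other seed matches, and the 2 other list tests. Leaving out genes under 300 bp and an estimated correlation for the 8mer genes were added after the data had been seen.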

Results

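The data comprised 10 poly(A) RNA-seq libraries of SH-SY5Y cells, a neuroblastoma line with a noradrenergic, neuroblast-like character, in 2 separate FPKM tables. The first held 3 libraries of cells given an siRNA against LncND and 3 given a scrambled siRNA. The second held 2 libraries of cells given a mimic of miR-143-3p, a double-stranded RNA that acts as the mature microRNA, and 2 given a scrambled miRNA. Estimated depth ranged from 25.6 to 44.0 M fragments in the siRNA table and from 13.8 to 37.6 M in the miRNA table. Within groups the log2 values of libraries correlated across genes at 0.988 to 0.996 in the siRNA table and at 0.997 in the miRNA table, against 0.962 to 0.967 and 0.966 to 0.968 between groups. LncND siRNA replicate 1 stood slightly apart, with correlations of 0.988 and 0.989 to the other 2 LncND siRNA libraries. No 2 libraries held the same values. Below, levels are mean FPKM ± SD with n = 3 per group for siRNA and n = 2 per group for the mimic. Numbers after them are log2 fold changes on the log2(FPKM + 1) scale, with ± SE where given, and adjusted p-values are from limma. Coordinates are hg19 as given in the tables.

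The first comparison asked how expression changed when LncND, a primate long non-coding RNA that the series title links to Notch signalling and to sequestration of a miRNA, was targeted by siRNA. All tested G1/S and G2/M cell cycle genes (30 each) fell and all 23 p53 target genes rose. Of neuronal differentiation genes 26 of 30 rose and of synaptic genes 25 of 33. Camera called these 5 lists with the preset correlation and none of them with an estimated one (adjusted p = 0.495 to 0.76). The microtubule regulator STMN4 rose from 2.58 ± 0.121 to 16.1 ± 0.767 FPKM. The cell cycle inhibitor CDKN1A rose from 81.9 ± 2.83 to 303 ± 10.6 FPKM (1.87 ± 0.045, adjusted p = 2.56e-09). In all, 8431 of 12601 genes (66.9%) changed, 4613 up and 3818 down, most of them by less than 1.5-fold. The balance turned to 3943 up and 4521 down under median-ratio scaling and to 4026 up and 4658 down under quantile normalization. A change of at least 1.5-fold was seen in 1554 genes, 1043 up and 511 down, and one of at least 2-fold in 323, of which 304 rose and 19 fell. Libraries of the 2 groups did not overlap for 70.9% of genes, against 10% by chance. LncND itself had no row and its level was not analysed here.

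The Notch receptors went in different directions with LncND siRNA. NOTCH1 (chromosome 9, 139388895 to 139440238) rose from 1.73 ± 0.14 to 2.44 ± 0.35 FPKM (0.33 ± 0.080, adjusted p = 0.00433). NOTCH2 (chromosome 1, 120454175 to 120612317) fell from 14.3 ± 0.648 to 9.23 ± 0.89 FPKM (-0.58 ± 0.063, adjusted p = 2.06e-05), and NOTCH3 (chromosome 19, 15270443 to 15311792) fell from 22 ± 1.37 to 13.5 ± 0.93 FPKM (-0.67 ± 0.058, adjusted p = 4.17e-06). NOTCH4 (chromosome 6, 32162619 to 32191844) was at 1.85 ± 0.0895 against 1.75 ± 0.0415 FPKM and did not pass (0.046 ± 0.055, adjusted p = 0.474). Of the transcription factors that act as Notch targets, HEY1 (chromosome 8, 80676244 to 80680098) rose from 10.7 ± 0.137 to 14.3 ± 0.702 FPKM (0.39 ± 0.043, adjusted p = 2.55e-05). HES1 (chromosome 3, 193853930 to 193856401) rose from 3.15 ± 0.341 to 4.15 ± 0.811 FPKM (0.30 ± 0.10, adjusted p = 0.026), but the call was lost without scrambled siRNA control replicate 2 (0.23, adjusted p = 0.102) and without LncND siRNA replicate 2 (0.18, 0.0795). It was also lost with no filter on low values (limma adjusted p = 0.0983) and under quantile normalization (0.2, 0.129), with a range of 0.00491 to 0.129 over all alternatives. The rise of NOTCH1 ended under quantile normalization (0.19, limma adjusted p = 0.0539, range 0.000337 to 0.0539). Among 31 tested Notch receptors, ligands and core machinery genes, 11 rose, 11 fell and 9 did not pass, or 13 and 11 adjusted over the list alone. Camera made no call (median 0.026, camera adjusted p = 0.715). The median and mean of that list were just above 0 while the camera direction was down. The ligand JAG2 rose from 1.23 ± 0.085 to 4.33 ± 0.214 FPKM (1.26). The gamma-secretase genes APH1B and PSEN2 rose by 0.97 and 0.68, and the coactivator MAML1 fell from 14.3 ± 0.257 to 8.69 ± 0.365 FPKM (-0.65). Of 14 tested Notch target genes, 3 rose, 6 fell and 5 did not pass, also when adjusted over the list alone (median -0.061, camera adjusted p = 0.411). CDKN1A, which is also a p53 target, was among those that rose. The transcription factor gene MYC fell from 18.9 ± 0.372 to 10.03 ± 0.326 FPKM (-0.85), the matrix gene TNC fell from 5.08 ± 0.288 to 2.58 ± 0.215 FPKM (-0.77) and NEURL1B fell from 7.03 ± 0.239 to 4.29 ± 0.226 FPKM (-0.60).

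**Figure D1:**
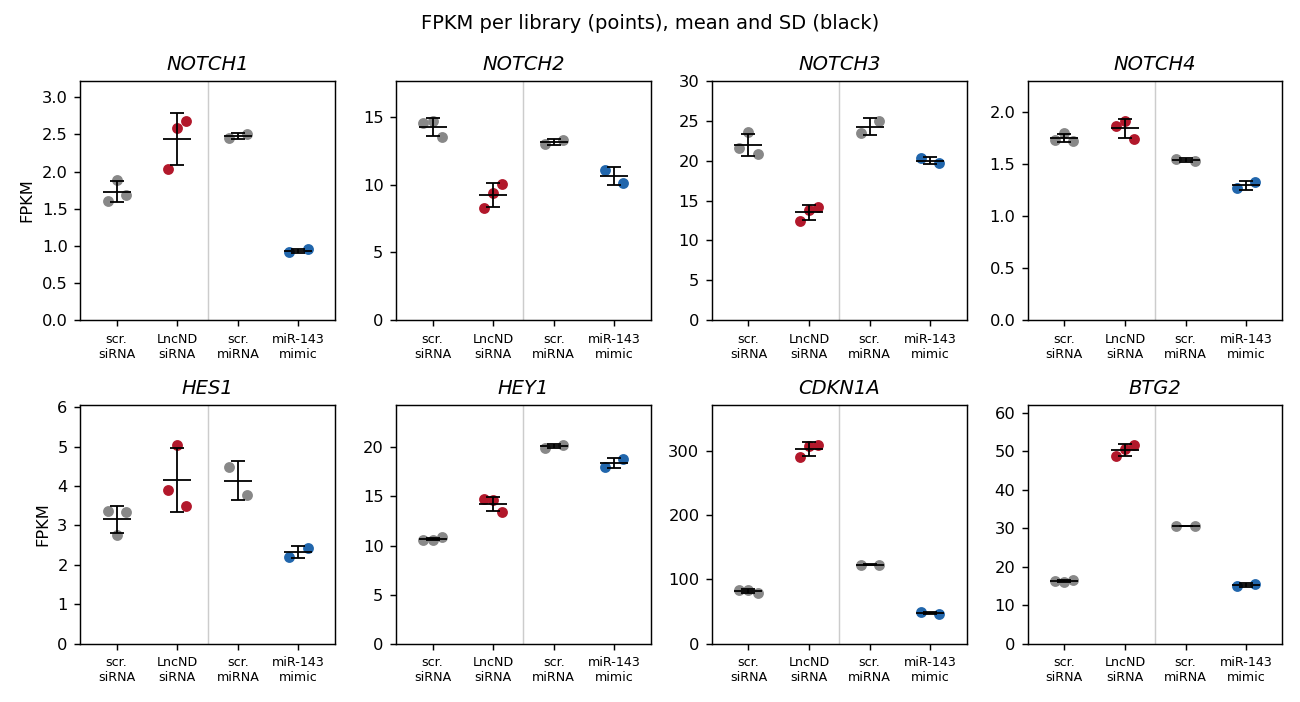
FPKM of NOTCH1 to NOTCH4, HES1, HEY1, CDKN1A and BTG2 in each library, with points for libraries and black bars for the mean and SD of a group (n = 3 for siRNA, left of the grey line, and n = 2 for miRNA, right of it). The 2 tables were made separately, so levels are compared only within a side, where NOTCH1 was at 2.44 against 1.73 FPKM with LncND siRNA and at 0.934 against 2.48 FPKM with the mimic.

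Genes of the cell cycle fell with LncND siRNA. All 30 G2/M genes fell, also when adjusted over the list alone (median -0.91, camera adjusted p = 1.99e-15, adjusted p = 0.76 with an estimated correlation). The proliferation marker MKI67 fell from 41.1 ± 1.16 to 17.5 ± 0.70 FPKM (-1.19 ± 0.041, adjusted p = 1.61e-08). The kinetochore gene CENPF fell from 60.3 ± 1.28 to 26.4 ± 0.513 FPKM (-1.17). The kinesin gene KIF20A fell from 29.9 ± 0.0663 to 14.3 ± 0.651 FPKM (-1.01) and the cytokinesis gene ANLN from 29.3 ± 1.15 to 13.8 ± 0.447 FPKM (-1.03). All 30 G1/S genes fell as well, also when adjusted over the list alone (median -0.64, camera adjusted p = 1.22e-12, adjusted p = 0.76 with an estimated correlation). The replicative helicase gene MCM2 fell from 59.4 ± 1.31 to 32.4 ± 1.79 FPKM (-0.86) and MCM4 from 42.3 ± 1.14 to 26.9 ± 0.774 FPKM (-0.63). UHRF1 fell from 36.9 ± 1.02 to 20.9 ± 0.875 FPKM (-0.79) and the DNA polymerase gene POLA1 from 9.98 ± 0.172 to 5.55 ± 0.145 FPKM (-0.74). All 23 tested p53 target genes rose, also when adjusted over the list alone (median 1.1, camera adjusted p = 1.22e-12, adjusted p = 0.495 with an estimated correlation). Besides CDKN1A, the antiproliferative gene BTG2 rose from 16.3 ± 0.249 to 50.4 ± 1.53 FPKM (1.57 ± 0.037, adjusted p = 2.43e-09). The ribonucleotide reductase subunit gene RRM2B rose from 7.4 ± 0.0653 to 25.6 ± 1.53 FPKM (1.66), and PHLDA3 rose from 21.1 ± 1.23 to 67.3 ± 1.62 FPKM (1.63). Of 22 apoptosis regulators, 10 rose, 6 fell and 6 did not pass, with 11 rising when adjusted over the list alone (median 0.065, camera adjusted p = 0.689). The proapoptotic genes BAX and BBC3, both also in the p53 list, rose by 1.1 and 0.92, DIABLO by 0.92 and CASP9 by 0.52.

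Of 30 tested neuronal differentiation genes, 26 rose, 1 fell and 3 did not pass, also when adjusted over the list alone (median 0.45, camera adjusted p = 4.41e-07, adjusted p = 0.495 with an estimated correlation). With STMN4 (2.26 ± 0.049, adjusted p = 2e-09), the secretory granule gene CHGB rose from 138 ± 4.81 to 310.3 ± 6.92 FPKM (1.17). SCG2 rose from 71.5 ± 4.65 to 174 ± 5.63 FPKM (1.27) and the growth cone gene GAP43 rose from 43.3 ± 2.03 to 85.9 ± 1.16 FPKM (0.97). Of 33 synaptic genes, 25 rose, 2 fell and 6 did not pass, also when adjusted over the list alone (median 0.41, camera adjusted p = 7.35e-06, adjusted p = 0.76 with an estimated correlation). The synaptic vesicle gene SYP rose from 15.2 ± 0.40 to 38.9 ± 0.415 FPKM (1.3) and RAB3A from 12.7 ± 0.177 to 30.7 ± 1.57 FPKM (1.21). The SNARE gene SNAP25 rose from 24.3 ± 0.447 to 66.6 ± 2.89 FPKM (1.42) and the NMDA receptor gene GRIN1 from 2.88 ± 0.149 to 7.47 ± 0.541 FPKM (1.12). The noradrenergic identity list made no call, with 28 tested genes of which 11 rose, 10 fell and 7 did not pass (median 0.073, camera adjusted p = 0.689). Its dopa decarboxylase gene DDC rose from 54 ± 2.03 to 111 ± 1.81 FPKM (1.03) and the receptor gene RET from 158 ± 3.96 to 309.9 ± 13.7 FPKM (0.96). Among 15 neural progenitor genes, 8 rose, 6 fell and 1 did not pass (median 0.21, camera adjusted p = 0.934). The mean and the test of this list pointed down while the median was above 0. MYCN rose from 1.07 ± 0.0917 to 4.16 ± 0.507 FPKM (1.31) and LIN28B from 4.43 ± 0.205 to 8.25 ± 0.613 FPKM (0.77), and SOX4 fell from 69.6 ± 1.21 to 45.1 ± 1.49 FPKM (-0.62). Of 19 mesenchymal-type genes, 10 rose, 7 fell and 2 did not pass (median 0.13, camera adjusted p = 0.715). The smooth muscle actin gene ACTA2 rose from 6.99 ± 0.574 to 28 ± 1.39 FPKM (1.86) and the matrix gene DCN from 16.1 ± 1.13 to 53 ± 1.98 FPKM (1.66). SPARC rose from 33.2 ± 1.2 to 57 ± 1.1 FPKM (0.76) and THY1 from 39.5 ± 0.945 to 67.4 ± 0.473 FPKM (0.76).

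The largest rise with LncND siRNA was that of PRAP1 (chromosome 10, 135160843 to 135166187), from 2.92 ± 0.498 to 45.6 ± 2.14 FPKM (3.58 ± 0.082, adjusted p = 2.06e-09). CRYM, the gene of the thyroid hormone-binding mu-crystallin (chromosome 16, 21269838 to 21314404), rose from 3.86 ± 0.128 to 29.3 ± 1.03 FPKM (2.64 ± 0.042, adjusted p = 3.73e-10). The sodium-activated potassium channel gene KCNT1 rose from 1.16 ± 0.138 to 11.1 ± 0.905 FPKM (2.48) and the neuropeptide gene NPB from 3.54 ± 0.462 to 23 ± 1.07 FPKM (2.41). ARHGAP36 rose from 11 ± 0.273 to 59.1 ± 1.68 FPKM (2.32) and the stress cytokine gene GDF15 from 2.12 ± 0.276 to 14.1 ± 0.554 FPKM (2.28). CILP2 rose from 1.23 ± 0.0917 to 9.44 ± 0.284 FPKM (2.23), and STMN4 was also among the 8. Among the largest falls, HNRNPA1P10 fell from 84.6 ± 6.88 to 11.6 ± 6.52 FPKM (-2.92 ± 0.32, adjusted p = 2.22e-05). RPS28 fell from 865 ± 34.5 to 365 ± 59.2 FPKM (-1.25). HNRNPA1P10 is named as a pseudogene of HNRNPA1, and its row spans 4131 bp (chromosome 12, 54674532 to 54678663). Whether its reads came from a copy or from HNRNPA1 itself was not tested. Ribosomal protein genes have many processed copies. Reads can be split between copies, so these values are uncertain. The division genes TOP2A and ASPM fell from 104 ± 1.4 to 46.1 ± 3.46 FPKM (-1.16) and from 21.3 ± 0.925 to 9.08 ± 0.102 FPKM (-1.14). The water channel gene AQP1 fell from 8.68 ± 0.484 to 3.41 ± 0.123 FPKM (-1.13), and MKI67 and CENPF were also among these genes.

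Among response lists, 15 interferon and double-stranded RNA response genes were tested, of which 8 rose, 2 fell and 5 did not pass, also when adjusted over the list alone (median 0.15, camera adjusted p = 0.341). IFI6 rose from 16.8 ± 1.51 to 35.7 ± 2.69 FPKM (1.04) and the transcription factor gene IRF9 from 8.67 ± 0.504 to 17.3 ± 0.70 FPKM (0.92), while IFIT5 fell from 5.05 ± 0.18 to 3.77 ± 0.124 FPKM (-0.34). Of 45 ribosomal protein genes, 2 rose, 17 fell and 26 did not pass, also when adjusted over the list alone (median -0.10, camera adjusted p = 0.0687). Without LncND siRNA replicate 1 that list passed (median -0.17, adjusted p = 0.000314), as it did with no filter on low values (0.0367), with a range of 0.000314 to 0.939 over all alternatives. RPL14 fell from 577 ± 20.6 to 273 ± 33.1 FPKM (-1.08). RPS13 and RPS25 fell by 0.82 and 0.72 and share the uncertainty of copies. Of 17 reported miR-143 target genes, 5 rose, 11 fell and 1 did not pass, also when adjusted over the list alone (median -0.20, camera adjusted p = 0.268). ADD3 and MDM2 rose by 0.89 and 0.73, and HK2 and DNMT3A both fell by 0.49. Over all 24 lists, camera called 5 with the preset correlation and 0 with an estimated correlation, where the lowest adjusted p was 0.495.

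The second comparison asked how expression changed when miR-143-3p was supplied as a mimic. All 30 G2/M and 28 of 30 G1/S genes fell, as did 18 of 23 p53 target genes and 21 of 22 cholesterol synthesis genes, while 18 of 30 neuronal differentiation genes rose. Camera called these 5 lists with the preset correlation and none of them with an estimated one (adjusted p = 0.413 for each). The neuroendocrine gene CHGA rose from 179 ± 11.8 to 650.4 ± 13.3 FPKM (1.85 ± 0.053, adjusted p = 1.88e-08) and the neuronal migration gene DCX from 11.7 ± 0.398 to 38.1 ± 0.593 FPKM (1.62 ± 0.049, adjusted p = 2.16e-08), while CDKN1A fell from 123 ± 0.623 to 47.6 ± 2.02 FPKM (-1.35 ± 0.045, adjusted p = 3.17e-08). In all, 7947 of 12558 genes (63.3%) changed, 3094 up and 4853 down. The balance depended on scaling, with 3974 up and 4033 down under median-ratio scaling and 4145 up and 3854 down under quantile normalization. A change of at least 1.5-fold was seen in 1646 genes, 500 up and 1146 down, and one of at least 2-fold in 344, 115 up and 229 down. Libraries of the 2 groups did not overlap for 81.9% of genes, against 33.3% by chance.

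With the mimic, NOTCH1 fell from 2.48 ± 0.0382 to 0.934 ± 0.0244 FPKM (-0.85 ± 0.083, adjusted p = 1.91e-05). NOTCH2 fell from 13.2 ± 0.238 to 10.6 ± 0.679 FPKM (-0.29 ± 0.059, adjusted p = 0.00209). NOTCH3 fell from 24.3 ± 1.04 to 20.01 ± 0.452 FPKM (-0.27 ± 0.051, adjusted p = 0.00123). NOTCH4 was at 1.3 ± 0.0419 against 1.54 ± 0.0178 FPKM and did not pass (-0.15 ± 0.085, adjusted p = 0.16). HES1 fell from 4.13 ± 0.496 to 2.32 ± 0.161 FPKM (-0.62 ± 0.088, adjusted p = 0.000193). HEY1 was at 18.4 ± 0.538 against 20.1 ± 0.225 FPKM and did not pass (-0.12 ± 0.049, adjusted p = 0.0506). It passed with the replicate number as a block (limma adjusted p = 0.0338) and without mimic replicate 2 (-0.15, 0.0423), the range being 0.0338 to 0.357 over alternatives. None of these 6 genes had a 7mer or 8mer miR-143-3p match in the 3′ UTR searched. Of 30 tested Notch receptors, ligands and core machinery genes, 6 rose, 10 fell and 14 did not pass, also when adjusted over the list alone (median -0.018, camera adjusted p = 0.776). The camera direction was up while the median and mean were below 0. The coactivator MAML3 rose from 8.6 ± 0.243 to 17.8 ± 0.103 FPKM (0.97) and the ubiquitin ligase gene MIB1 from 14.4 ± 0.424 to 21.1 ± 0.163 FPKM (0.53). The ligand DLL3 fell from 5.8 ± 0.34 to 2.82 ± 0.14 FPKM (-0.83). Of 14 Notch target genes, 1 rose, 8 fell and 5 did not pass, or 2 and 9 adjusted over the list alone (median -0.37, camera adjusted p = 0.072). The list passed camera without scrambled miRNA control replicate 1 (median -0.38) or 2 (median -0.36), each of which leaves 1 control library. Over alternatives the adjusted p ranged from 0.00463, given by fry, to 0.517. HES6 fell from 51 ± 0.282 to 26.7 ± 0.090 FPKM (-0.91) and HES7 from 4.71 ± 0.114 to 0.903 ± 0.168 FPKM (-1.59), and GATA3 rose from 75.9 ± 1.91 to 116 ± 0.666 FPKM (0.60).

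All 30 G2/M genes fell with the mimic, also when adjusted over the list alone (median -0.85, camera adjusted p = 7.35e-13, adjusted p = 0.413 with an estimated correlation). HMMR fell from 32.4 ± 0.807 to 8.82 ± 0.448 FPKM (-1.77 ± 0.054, adjusted p = 2.16e-08). The mitotic kinase genes AURKB and CDK1 fell from 49.4 ± 0.34 to 19 ± 1.02 FPKM (-1.33) and from 74.9 ± 1.35 to 30.5 ± 2.09 FPKM (-1.27). CDC20 fell from 74.1 ± 1.1 to 34.2 ± 0.843 FPKM (-1.1). Of 30 G1/S genes, 0 rose, 28 fell and 2 did not pass, or 29 falling adjusted over the list alone (median -0.48, camera adjusted p = 5.53e-07, adjusted p = 0.413 with an estimated correlation). RRM2 fell from 77.3 ± 1.46 to 46.3 ± 1.54 FPKM (-0.73) and PCNA from 127 ± 0.877 to 75.6 ± 4.94 FPKM (-0.74). Of 23 p53 target genes, 2 rose, 18 fell and 3 did not pass, also when adjusted over the list alone (median -0.44, camera adjusted p = 0.000217, adjusted p = 0.413 with an estimated correlation). The death receptor gene TNFRSF10B fell from 41.4 ± 0.279 to 15.9 ± 0.274 FPKM (-1.33). BTG2 fell from 30.5 ± 0.0451 to 15.2 ± 0.503 FPKM (-0.96) and GADD45A from 26.4 ± 0.162 to 14.4 ± 0.174 FPKM (-0.83). Of 22 apoptosis regulators, 6 rose, 10 fell and 6 did not pass, with 7 rising when adjusted over the list alone (median -0.13, camera adjusted p = 0.899). The antiapoptotic genes MCL1 and BCL2L1 rose by 0.89 and 0.54, and PMAIP1 fell from 16.4 ± 0.119 to 8.14 ± 1.59 FPKM (-0.94). Of 22 cholesterol synthesis genes, 21 fell and 1 did not pass, also when adjusted over the list alone (median -0.43, camera adjusted p = 2.22e-05, adjusted p = 0.413 with an estimated correlation). The cholesterol carrier gene STARD4 fell from 70.8 ± 4.02 to 26.9 ± 0.736 FPKM (-1.36) and the squalene synthase gene FDFT1 from 78.5 ± 0.484 to 45.9 ± 1.01 FPKM (-0.76). DHCR7 fell from 36.5 ± 0.171 to 21.6 ± 0.682 FPKM (-0.73) and HSD17B7 from 9.87 ± 0.245 to 4.87 ± 0.274 FPKM (-0.89).

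Of 30 neuronal differentiation genes, 18 rose, 6 fell and 6 did not pass with the mimic, also when adjusted over the list alone (median 0.37, camera adjusted p = 6.26e-05, adjusted p = 0.413 with an estimated correlation). Besides CHGA and DCX, DPYSL3 rose from 124 ± 1.04 to 248 ± 1.94 FPKM (0.99) and STMN4 from 6.37 ± 0.277 to 17.6 ± 0.575 FPKM (1.34). Of 28 noradrenergic identity genes, 16 rose, 7 fell and 5 did not pass, with 17 rising adjusted over the list alone (median 0.21, camera adjusted p = 0.00359, adjusted p = 0.413 with an estimated correlation). The vesicular monoamine transporter gene SLC18A1 rose from 64.7 ± 1.65 to 181 ± 3.38 FPKM (1.47) and DDC from 91.1 ± 0.254 to 231 ± 7.99 FPKM (1.34). The transcription factor gene HAND1 rose from 47.7 ± 2.68 to 107 ± 1.02 FPKM (1.14), while RET fell from 280.1 ± 8.04 to 133 ± 3.82 FPKM (-1.07). Synaptic genes went both ways, with 34 tested of which 13 rose, 11 fell and 10 did not pass (median 0.040, camera adjusted p = 0.248). The vesicle release genes CPLX2 and SV2A fell by 0.78 and 0.67, and the synaptotagmin gene SYT11 rose from 48.8 ± 1.04 to 73.4 ± 1.08 FPKM (0.58). Of 15 neural progenitor genes, 4 rose, 7 fell and 4 did not pass (median -0.094, camera adjusted p = 0.97). ID3 fell from 52.7 ± 0.487 to 26.8 ± 0.134 FPKM (-0.95) and ID2 rose from 30.3 ± 0.45 to 59.5 ± 3.49 FPKM (0.95). Of 18 mesenchymal-type genes, 2 rose, 14 fell and 2 did not pass, also when adjusted over the list alone (median -0.48, camera adjusted p = 0.0137, adjusted p = 0.423 with an estimated correlation). The receptor gene PDGFRB fell from 22.3 ± 0.392 to 7.3 ± 0.16 FPKM (-1.49) and LUM from 34.8 ± 0.671 to 17.8 ± 0.665 FPKM (-0.93). ACTA2 fell from 10.9 ± 0.905 to 4.73 ± 0.0481 FPKM (-1.05) and COL6A2 rose from 48 ± 0.71 to 73.3 ± 0.0129 FPKM (0.60). This call was lost among genes of at least 5 FPKM (median -0.36, camera adjusted p = 0.0703). Over alternatives the adjusted p ranged from 0.00555, given by fry, to 0.423, given by camera with an estimated correlation.

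Among response lists, camera called immediate early, unfolded protein response and heat shock genes down with the mimic and made no call for interferon and hypoxia response genes. Of 15 immediate early genes, 1 rose, 11 fell and 3 did not pass, also when adjusted over the list alone (median -0.36, camera adjusted p = 0.015, adjusted p = 0.413 with an estimated correlation). EGR1 fell from 10.3 ± 0.302 to 3.64 ± 0.0719 FPKM (-1.29) and CYR61 from 4.56 ± 0.0621 to 1.26 ± 0.0785 FPKM (-1.3). The call was lost among genes of at least 5 FPKM (median -0.27, camera adjusted p = 0.109). Over alternatives the adjusted p ranged from 0.00283, given by fry, to 0.413, given by camera with an estimated correlation. Of 26 unfolded protein response genes, 5 rose, 17 fell and 4 did not pass, with 18 falling adjusted over the list alone (median -0.25, camera adjusted p = 0.0191, adjusted p = 0.413 with an estimated correlation). The endoplasmic reticulum chaperone genes CALR and PDIA6 fell from 390.4 ± 5.34 to 187 ± 0.127 FPKM (-1.06) and from 253 ± 2.35 to 127 ± 1.49 FPKM (-0.99). Of 14 heat shock genes, 2 rose, 11 fell and 1 did not pass, also when adjusted over the list alone (median -0.34, camera adjusted p = 0.0279, adjusted p = 0.698 with an estimated correlation). HSPA4L fell from 21.3 ± 0.931 to 9.8 ± 0.733 FPKM (-1.04). Of 45 ribosomal protein genes, 23 rose, 2 fell and 20 did not pass, also when adjusted over the list alone (median 0.16, camera adjusted p = 2.87e-05, adjusted p = 0.698 with an estimated correlation). RPL15 rose from 395 ± 7.4 to 629.6 ± 23.5 FPKM (0.67) and RPL13 from 157 ± 0.797 to 244 ± 5.94 FPKM (0.63). The call was lost under quantile normalization (median 0.043, adjusted p = 0.231, range 4.93e-07 to 0.698). Of 14 interferon response genes, 3 rose, 6 fell and 5 did not pass (median -0.062, camera adjusted p = 0.843). HERC5 fell from 9.74 ± 0.959 to 4.55 ± 0.00549 FPKM (-0.95) and USP18 from 7.43 ± 0.712 to 2.48 ± 0.574 FPKM (-1.29). Over all 24 lists camera called 12, 3 up and 9 down, and 0 with an estimated correlation, where the lowest adjusted p was 0.413.

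**Figure D2:**
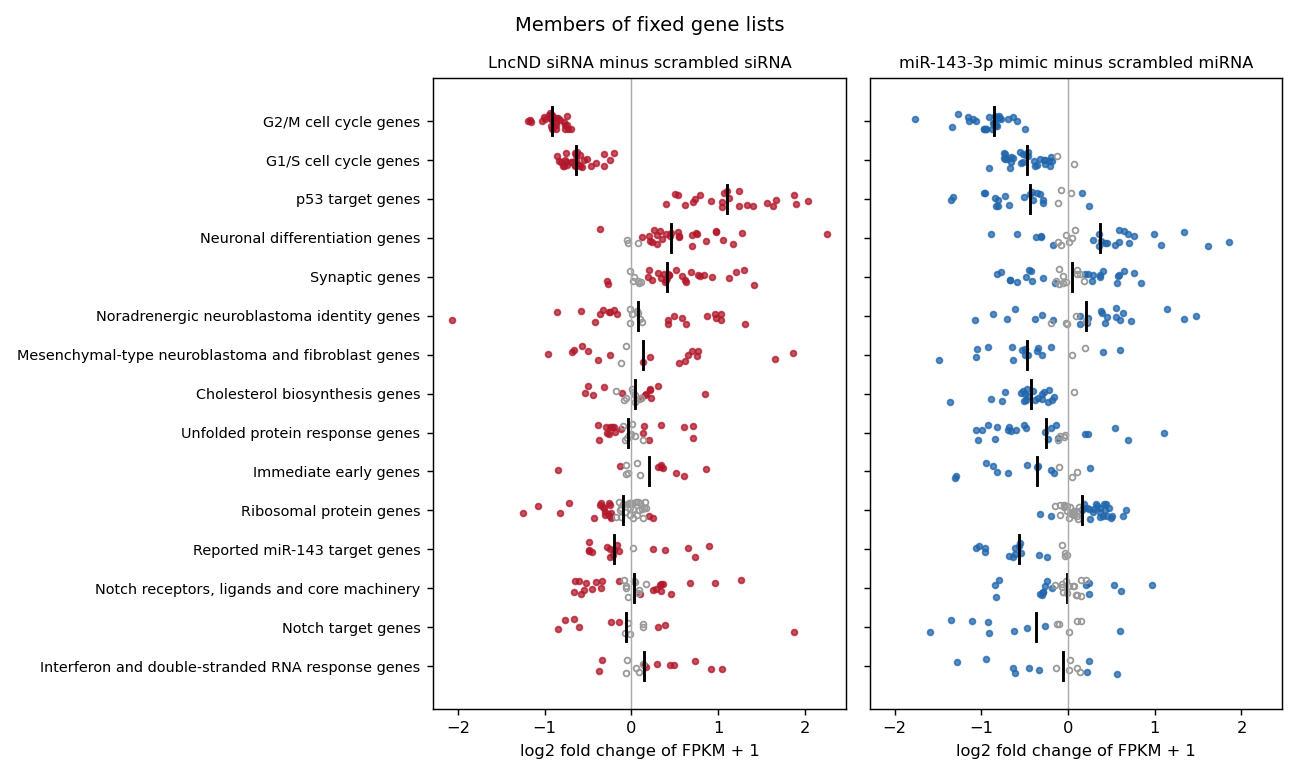
Log2 fold changes (FPKM + 1) of the members of 15 fixed gene lists with LncND siRNA (left) and the miR-143-3p mimic (right). Points are genes, filled where limma passed and open where not, and black bars are list medians, such as 1.1 and -0.44 for p53 target genes and -0.91 and -0.85 for G2/M genes.

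The largest rises with the mimic in genes of ordinary length were those of SLC35D3 (chromosome 6, 137243401 to 137246776), from 2.69 ± 0.0278 to 35 ± 1.22 FPKM (3.29 ± 0.056, adjusted p = 2.31e-09), and of ELFN1. The latter, a synaptic adhesion gene (chromosome 7, 1748797 to 1787590), rose from 4.12 ± 0.115 to 36.8 ± 0.478 FPKM (2.88 ± 0.052, adjusted p = 2.31e-09). The chemokine receptor gene CXCR4 rose from 9.13 ± 0.318 to 55.1 ± 2.28 FPKM (2.47). The serotonin receptor gene HTR1E rose from 1.71 ± 0.279 to 11.5 ± 0.885 FPKM (2.21) and the adhesion scaffold gene NEDD9 from 4.8 ± 0.452 to 25.2 ± 0.82 FPKM (2.17). SNORD58C, a small nucleolar RNA gene far shorter than a sequenced fragment, was listed at 201 and 837 FPKM in the mimic libraries and at the lowest value of 0.001 in both controls, so no fold is given. The pseudogene TFAMP1 rose from 0.988 ± 0.123 to 11.9 ± 0.70 FPKM (2.69) and the histone gene H3F3A from 2.87 ± 4.06 to 11.7 ± 0.736 FPKM (2.28). Both share sequence with other copies and are uncertain. The controls of H3F3A were at 0.00129 and 5.74 FPKM, and its log2 fold change was 0.91 without scrambled miRNA control replicate 1 and 3.66 without replicate 2. Its call was lost with a robust prior (limma adjusted p = 0.275) and with no filter on low values (0.132), the range being 3.42e-12 to 0.275. ECEL1 (chromosome 2, 233344536 to 233352532) fell most, from 38.7 ± 0.187 to 7.5 ± 1.39 FPKM (-2.23 ± 0.091, adjusted p = 1.04e-07). The urea cycle gene ASS1 (chromosome 9, 133320093 to 133376661) fell from 15.5 ± 0.0685 to 2.59 ± 0.0733 FPKM (-2.2 ± 0.060, adjusted p = 1.7e-08). The tropomyosin gene TPM3 (chromosome 1, 154127779 to 154164609) fell from 179.7 ± 3.0 to 42.9 ± 3.16 FPKM (-2.04 ± 0.053, adjusted p = 1.3e-08). The retinoic acid carrier gene CRABP2 fell from 57 ± 1.91 to 13.2 ± 0.94 FPKM (-2.04) and the cadherin gene CDH11 from 19.98 ± 0.438 to 4.26 ± 0.0951 FPKM (-2.0). The protease inhibitor gene TFPI2 fell from 129 ± 0.853 to 32.2 ± 1.78 FPKM (-1.97) and LAYN from 10.9 ± 0.506 to 2.14 ± 0.32 FPKM (-1.92). KDM5B-AS1 fell from 14.6 ± 2.7 to 3.13 ± 0.234 FPKM (-1.9). Because the strand setting of the quantification is not given, its reads cannot be told from those of the gene on the other strand. TPM3 and CDH11 carried an 8mer miR-143-3p match in the 3′ UTR, and ECEL1, ASS1, CRABP2, TFPI2 and LAYN carried none.

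Genes with a miR-143-3p match in the 3′ UTR were lower with the mimic than genes without. Of 581 genes with the 8mer match TCATCTCA, 288 fell (49.6%) and 92 rose (15.8%), against 36.9% and 26.5% of the 8869 genes without any match. Camera set them against all other genes with a UTR (adjusted p = 0.0125, and 0.539 with an estimated correlation). Their median log2 fold change was -0.16, against -0.048 for genes without any match. That difference of -0.11 was -0.055 with no filter on low values, where camera still called the 8mer genes (adjusted p = 0.0342, range 0.00253 to 0.539 over alternatives). With UTR length and GC content in the model the effect of an 8mer match was -0.202 (95% interval -0.24 to -0.17). This interval and those of the same model below take genes as independent and do not measure the spread between libraries. Medians for genes whose best match was a 7mer-m8 or a 7mer-A1 were -0.14 and -0.10. Of 17 reported miR-143 target genes tested, 0 rose, 13 fell and 4 did not pass, also when adjusted over the list alone (median -0.56, camera adjusted p = 0.000289, adjusted p = 0.413 with an estimated correlation). The actin-bundling gene FSCN1 fell from 199 ± 2.47 to 102 ± 1.34 FPKM (-0.96 ± 0.041, adjusted p = 1.24e-07). ADD3 fell from 54.2 ± 3.63 to 27.3 ± 0.777 FPKM (-0.96), the collagen gene COL5A1 from 3.23 ± 0.0695 to 1.03 ± 0.0425 FPKM (-1.06) and MDM2 from 17.7 ± 0.108 to 10.7 ± 0.507 FPKM (-0.68). In the UTRs searched, ADD3 and COL5A1 had a 7mer-m8 match, FSCN1 and MDM2 had only 7mer-A1 matches, and none of them had an 8mer match. With LncND siRNA, 195 of 574 genes with an 8mer match rose (34.0%) and 184 fell (32.1%), against 38.4% and 29.4% of genes without a match. Camera, against all other genes with a UTR, did not call them (adjusted p = 0.589). Their median was 0.0014, against 0.034 for genes without a match. That difference of -0.033 was -0.0079 with no filter on low values, -0.017 without LncND siRNA replicate 1 and -0.062 for 7mer-m8 or 8mer matches, with no call in any setting (camera adjusted p from 0.177 to 0.922). With UTR length and GC content in the model the effect was 0.020 (95% interval -0.013 to 0.054) for 8mer matches and -0.031 (-0.052 to -0.0092) for 7mer-m8 or 8mer matches.

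**Figure D3:**
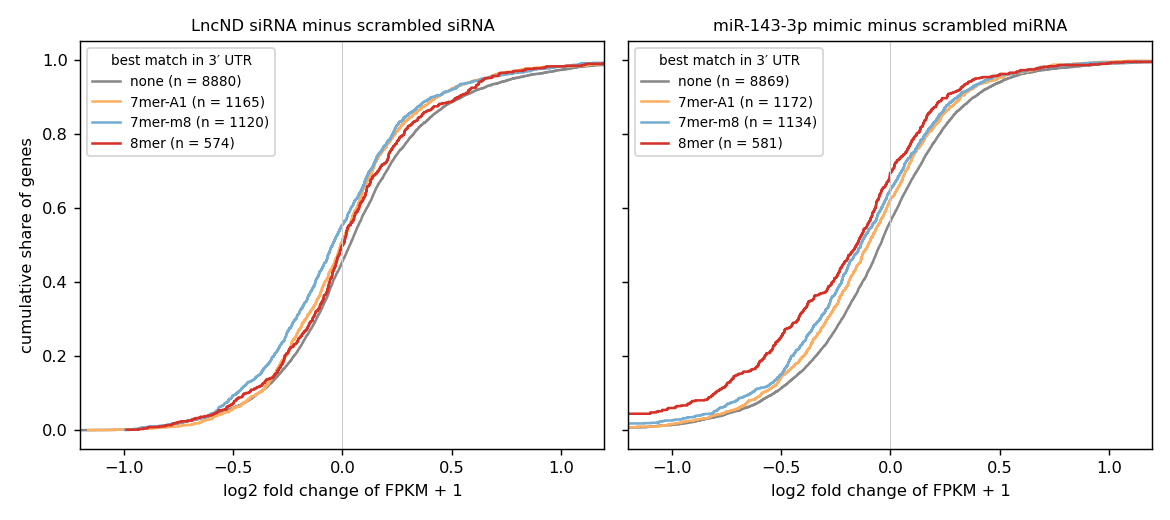
Cumulative share of genes (vertical axis) against log2 fold change of FPKM + 1 (horizontal axis) with LncND siRNA (left) and the miR-143-3p mimic (right), for genes grouped by their best miR-143-3p match in the 3′ UTR. With the mimic the curves of matched genes lie to the left, with medians of -0.16 for 8mer and -0.048 for no match, and with LncND siRNA the medians are 0.0014 and 0.034.

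The third comparison asked whether targeting LncND and supplying miR-143-3p moved the same genes, since the title describes LncND as sequestering miRNA. Of 5464 genes called in both, 3579 (65.5%) changed in the same direction. Genes that rose in both numbered 1552, against 1105 for independent lists (odds ratio 2.27, 95% interval 2.08 to 2.47, Fisher's exact p = 4.98e-82). Those that fell in both numbered 2027, against 1464 (odds ratio 2.44, 2.25 to 2.64, Fisher's exact p = 4.14e-111). The p-values and intervals of Fisher's test take genes as independent and do not measure the spread between libraries. With changes of at least 1.5-fold, 233 genes fell in both, against 45.4 for independent lists, and 103 rose in both, against 36.6. As many, 103, rose with siRNA and fell with the mimic, against 86.9 (odds ratio 1.23, 0.98 to 1.52, Fisher's exact p = 0.0611). Fold changes correlated across genes at 0.219 (Pearson) and 0.253 (Spearman), genes not being independent replicates. The GTPase gene RHOB rose by 1.45 with siRNA and 1.72 with the mimic, and DDC by 1.03 and 1.34. The tetraspanin gene CD9 rose by 1.13 and 1.51, STMN4 by 2.26 and 1.34, and the microtubule gene MAP6 by 1.2 and 1.2. The actin-binding gene CNN2 fell by 0.85 and 1.85. Effects differed for 7416 of 12327 genes, being higher with siRNA for 4699 and with the mimic for 2717, and the balance turned to 3502 and 3995 under median-ratio scaling. TFPI2 differed by 3.54 ± 0.069 (adjusted p = 2.55e-12) and CDKN1A by 3.22 ± 0.065 (adjusted p = 2.55e-12). BTG2 differed by 2.52 ± 0.057 (adjusted p = 6.62e-12) and the cytokine receptor gene TNFRSF12A by 3.1 ± 0.071 (adjusted p = 6.62e-12). These 4 rose with siRNA and fell with the mimic. NEDD9 differed by -3.1 ± 0.079 (adjusted p = 2.19e-11) and CXCR4 by -3.34 ± 0.088 (adjusted p = 2.26e-11), in the opposite sense. The p53 target list differed between the comparisons, with a median difference of 1.52 (camera adjusted p = 8.73e-14, and adjusted p = 0.203 with an estimated correlation).

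**Figure D4:**
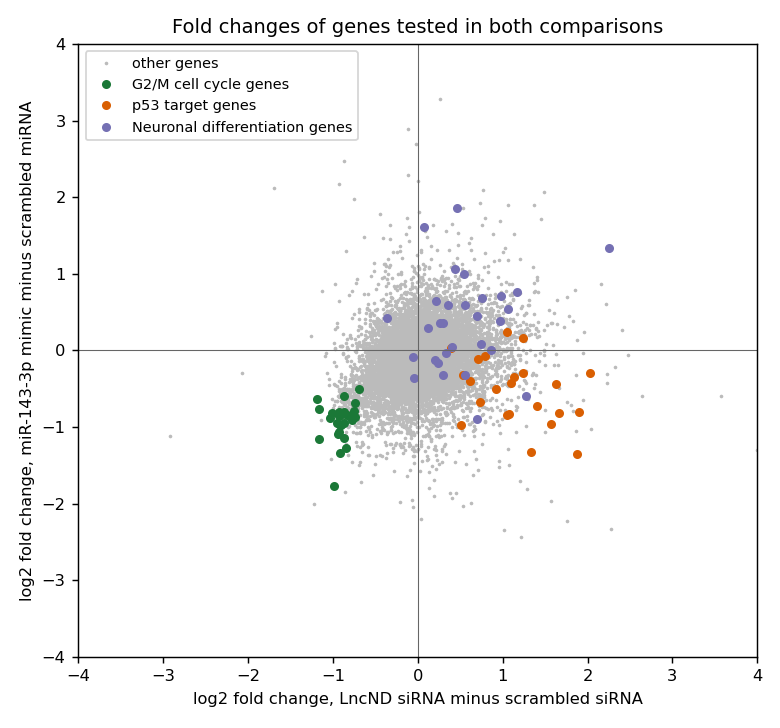
Log2 fold changes of FPKM + 1 for the 12327 genes tested in both tables, LncND siRNA on the horizontal and the miR-143-3p mimic on the vertical axis, with 1 gene outside the axes. G2/M genes (green) lie low in both, p53 target genes (orange) to the right and mostly below 0, and neuronal differentiation genes (violet) mostly to the right.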

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

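The tests of miR-143-3p matches in the siRNA comparison were chosen only after the result was seen. The other tests in this part were planned. The results below were singled out because the effect of LncND siRNA and the effect of the mimic differed by a limma or camera test of the difference itself.

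Among Notch genes, NOTCH1 changed by 0.33 with LncND siRNA and by -0.85 with the mimic, a difference of 1.18 (95% interval 0.92 to 1.43, limma adjusted p = 1.91e-06). HES1 differed by 0.92 (0.59 to 1.26, 0.000219) and HEY1 by 0.51 (0.37 to 0.65, 1.85e-05), both higher with siRNA. NOTCH2 differed by -0.29 (-0.5 to -0.088, 0.0173) and NOTCH3 by -0.40 (-0.58 to -0.21, 0.00132), each falling in both comparisons and further with siRNA. The calls of NOTCH1 and HES1 in the siRNA comparison ended under quantile normalization.

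Among gene lists, the median difference was 1.52 for p53 target genes (camera adjusted p = 8.73e-14), 0.54 for synaptic genes (0.00109), 0.43 for cholesterol synthesis genes (0.000706), 0.40 for mesenchymal-type genes (0.0404), 0.76 for immediate early genes (0.0374), -0.11 for G1/S genes (0.00667) and -0.33 for ribosomal protein genes (1.84e-07). With an estimated correlation none of the 24 lists passed, the lowest adjusted p being 0.203.

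The rise of all 23 tested p53 target genes with LncND siRNA was weighed against technical sources. Scaling by the authors was argued against, since the list median was at least 1.04 under both median-ratio scaling and quantile normalization, against 1.1 as deposited. A single library was argued against as well, since without LncND siRNA replicate 1, where RNY4 held most of the summed FPKM, the median was 1.12. Whether loss of LncND or another effect of the siRNA lay behind the rise stays open, because the labels describe the siRNA as a single treatment. A biological response to LncND loss is 1 hypothesis and may be separated from the others by a second siRNA sequence.

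The fall of genes with a miR-143-3p match with the mimic was weighed against sequence features of the UTR. UTR length and GC content were argued against as the whole source, since the effect of an 8mer match was -0.155 without them and -0.202 with both in the model (95% interval -0.24 to -0.17). The interval takes genes as independent, and camera with an estimated correlation did not call these genes (adjusted p = 0.539). A feature common to any short word was argued against too, since the 7mer-m8 match took rank 1 of 15909 words. Direct action of the mimic is a hypothesis consistent with both values. For LncND siRNA, release of miR-143-3p predicts a fall of such genes. The effect of an 8mer match was 0.020 (-0.013 to 0.054), while that of 7mer-m8 or 8mer matches was -0.031 (-0.052 to -0.0092). There the 7mer-m8 match took rank 510 of 15904 words with UTR length and GC content removed, and rank 2520 as fitted. Many other words thus had a lower statistic. Among them CATCTCT, which holds the part CATCTC of the match, took rank 4 with siRNA (z = -6.62) and rank 3 with the mimic (z = -8.11). TGCTCCA, at rank 1 with siRNA, does not hold that part, and these values do not decide.

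As a further value, the correlation of fold changes between the comparisons was 0.220 across 11555 genes after trends with gene length, UTR length, GC content and expression level were removed, against 0.225 before. Of the 10 splits of the 6 siRNA libraries into 3 and 3, the real one called 8431 genes and the highest of the others 1. So 1 split gave as many, and 10 splits are too few for a share under 0.05. Every other split mixes treated and control libraries, which puts the treatment difference into the spread within groups. Their low counts follow from that and are not a null count.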

How the results depend on the processing

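Leaving out genes under 300 bp and the estimated correlation for 8mer genes were chosen after the data had been seen. The other settings were planned before the data were examined. The count of genes changed with LncND siRNA ranged from 6393 to 9243 and that with the mimic from 6280 to 8247 over changes of pseudocount, filter, scaling, limma prior and block, and fell to 1554 and 1646 with a fold change of at least 1.5, by construction. Leaving out 1 library at a time gave 7713 to 8599 and 6775 to 7599 genes, 3083 to 3730 in the same direction in both, 6567 to 7534 whose effects differed, correlations of 0.2004 to 0.235 and 5 to 6 and 12 to 13 called lists. In the mimic comparison this leaves 1 library in an arm, assumed to vary like the others. With an estimated correlation camera called 0 lists in both comparisons, against 5 and 12, and fry, which asks another question, called 14 and 19. Camera with an estimated correlation rests on few residual degrees of freedom, so these losses need not come from genes that vary together. The median difference of 8mer genes with the mimic, -0.11, did not pass with an estimated correlation (adjusted p = 0.539). The Notch receptor, ligand and core machinery list had a median of -0.018 with the mimic. There fry called a fall (adjusted p = 0.0186) and camera leaned up without passing. fry sets the list against 0 and camera against other genes, and the median over all tested genes was -0.062. The 2 directions thus answer different questions and need not conflict.

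Named genes kept their side of the threshold and direction in 1211 of 1214 values under other settings with siRNA and in 1228 of 1234 with the mimic, and in 736 of 738 and 498 of 500 values without 1 library. The exceptions with siRNA were HES1 and NOTCH1. With the mimic H3F3A and S100B were lost, and NOTCH4 and HEY1 were gained. S100B was lost without scrambled miRNA control replicate 1 (-0.23, adjusted p = 0.0677) and with no filter (0.0604), the range over alternatives being 0.00142 to 0.0677. A change of sign between values that passed on neither side was not counted as a reversal. The causes were not tested.

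In the siRNA table replicate numbers did not pair all libraries. Deviations of same-numbered siRNA libraries correlated at 0.068, 0.207 and -0.053, and not every library correlated best with its own number. The 2 miRNA pairs gave 0.135 each, but with 2 libraries per group the values mirror each other, so pairing there stays undecided. With the replicate number as a block, 8022 genes were called with siRNA, 8247 with the mimic, 3557 in the same direction and 7123 as different, and HEY1 passed with the mimic (adjusted p = 0.0338). Depth limits what can be said of genes near 1 FPKM, most of all in mimic replicate 2 and scrambled miRNA control replicate 1, which held an estimated 13.8 and 14.4 M fragments.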

Other observations

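The tests of the leading short word in the siRNA comparison were chosen only after the result was seen. Other gene groups were tested with both treatments and are given here with camera and limma adjusted p-values. Glucose and oxygen genes went both ways. Of 19 hypoxia response genes, 9 rose, 5 fell and 5 did not pass with LncND siRNA (median 0.11, camera adjusted p = 0.737), and 6 rose, 9 fell and 4 did not pass with the mimic (median -0.11, camera adjusted p = 0.572). With the mimic the median of this list was below 0 while the mean and the test were above. ANGPTL4 rose from 0.613 ± 0.15 to 6.58 ± 0.547 FPKM (2.23) with siRNA. With the mimic the growth factor gene VEGFA rose from 42 ± 0.197 to 92.8 ± 0.287 FPKM (1.12) and ADM from 3.28 ± 0.615 to 9.32 ± 0.476 FPKM (1.28). VEGFA fell from 31.8 ± 0.759 to 23.9 ± 0.364 FPKM (-0.40) with siRNA. Of 19 glycolysis genes, 4 rose, 7 fell and 8 did not pass with LncND siRNA (median -0.062, camera adjusted p = 0.689), and 2 rose, 6 fell and 11 did not pass with the mimic (median 0.0019, camera adjusted p = 0.977). With the mimic the mean and the test lay below 0 and the median just above. The glucose transporter gene SLC2A1 fell from 26.3 ± 0.679 to 15 ± 0.448 FPKM (-0.77) with siRNA, and the glycolytic gene PGK1 fell from 295 ± 3.53 to 128 ± 5.3 FPKM (-1.2) with the mimic. The 22 cholesterol synthesis genes, all but 1 of which fell with the mimic, gave 8 rose, 5 fell and 9 did not pass with siRNA (median 0.040, camera adjusted p = 0.976). TM7SF2 rose from 24.9 ± 0.315 to 45.4 ± 1.59 FPKM (0.84).

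Axon guidance genes numbered 32 and 34 tested, of which 15 rose, 10 fell and 7 did not pass with LncND siRNA (median 0.053, camera adjusted p = 0.689), and 9 rose, 12 fell and 13 did not pass with the mimic (median -0.046, camera adjusted p = 0.977). SEMA3D rose from 0.153 ± 0.0251 to 2.59 ± 0.133 FPKM (1.64) with siRNA. The receptor gene EPHA2 rose from 6.75 ± 0.26 to 11.7 ± 0.36 FPKM (0.71) with siRNA and fell from 11.3 ± 0.695 to 3.19 ± 0.344 FPKM (-1.56) with the mimic. SLIT2 fell from 3.24 ± 0.226 to 0.315 ± 0.0236 FPKM (-1.69) with the mimic. Of 13 RNA interference genes, 2 rose, 6 fell and 5 did not pass with LncND siRNA (median -0.13, camera adjusted p = 0.403), and 6 rose, 3 fell and 4 did not pass with the mimic (median 0.18, camera adjusted p = 0.248), with 5 falling with siRNA when adjusted over the list alone. The nuclear export gene XPO5 fell by 0.59 with siRNA and by 0.41 with the mimic. The argonaute gene AGO2 fell from 8.5 ± 0.469 to 5.45 ± 0.894 FPKM (-0.57) with siRNA and rose from 6.0 ± 0.715 to 8.69 ± 0.15 FPKM (0.47) with the mimic. Of 11 genes at 2p25.3, around the neuronal transcription factor gene MYT1L, 5 rose, 3 fell and 3 did not pass with LncND siRNA (median 0.11, camera adjusted p = 0.934), and 3 rose, 3 fell and 5 did not pass with the mimic (median -0.0011, camera adjusted p = 0.642). MYT1L rose from 3.9 ± 0.129 to 5.66 ± 0.477 FPKM (0.44) with siRNA and from 2.4 ± 0.16 to 6.12 ± 0.379 FPKM (1.07) with the mimic, and PXDN fell by 0.45 and 0.28. The median of that list with the mimic changed sign under both scaling alternatives.

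With LncND siRNA, of 14 immediate early genes 7 rose, 2 fell and 5 did not pass (median 0.20, camera adjusted p = 0.387), of 14 heat shock genes 2 rose, 8 fell and 4 did not pass (median -0.19, camera adjusted p = 0.245), and of 26 unfolded protein response genes 7 rose, 10 fell and 9 did not pass (median -0.036, camera adjusted p = 0.689), the mean of the last lying above 0. ARC rose by 0.86 and DDIT3 by 0.61. Among 14 reference genes often used for normalization, 2 rose, 3 fell and 9 did not pass with LncND siRNA (median 0.0065, camera adjusted p = 0.689), and 2 rose, 9 fell and 3 did not pass with the mimic (median -0.23, camera adjusted p = 0.151), with 1 rising with siRNA when adjusted over the list alone, and the median with siRNA changed sign under both scaling alternatives. RPL13A fell from 353 ± 13 to 223 ± 23.4 FPKM (-0.66) with siRNA, and PGK1, B2M and HPRT1 fell by 1.2, 0.62 and 0.49 with the mimic. For lists in this part, counts adjusted over the list alone were otherwise those given. Markers of other cell types were mostly under 1 FPKM. Those tested were PMP22, S100B and PDGFRA of the Schwann and glial list, which changed by 0.91, 0.77 and -0.57 with siRNA and by 0.68, -0.35 and -0.35 with the mimic. The others were CD68, 3.07 ± 0.255 against 1.01 ± 0.087 FPKM with siRNA, and the epithelial genes MUC1, 9.03 ± 0.226 against 2.52 ± 0.094 FPKM, and CLDN4, 2.17 ± 0.23 against 0.621 ± 0.0504 FPKM, of which MUC1 was at 1.95 ± 0.135 against 1.79 ± 0.0202 FPKM with the mimic.

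With UTR length and GC content removed, the 7-base word with the lowest rank-sum statistic with LncND siRNA was TGCTCCA, present in the UTRs of 1540 genes (effect -0.089, 95% interval -0.11 to -0.067, rank-sum z = -8.35, against a lowest z of -4.62 over 20 permutations). It was picked from 15904 words on these same fold changes, which biases its effect and interval away from 0. The permutations shuffled values over genes and so removed any correlation between genes, which can make their limit too lenient. With the mimic GGATTAC reached z = -6.79, also beyond the lowest permuted z of -4.55. TGCTCCA took rank 2069 of 15909 with the mimic. Of the 10 lowest words with siRNA, others also hold its part GCTCC, such as ATGCTCC (z = -7.20), TGCTCCT (-6.88) and CTGCTCC (-6.01). CATCTCT (-6.62) and ATCTCTA (-5.60) do not. Words that overlap can stand at the same sites, so they are not independent. No word with GCTCC was among the 10 lowest with the mimic. A candidate explanation is the seed of an siRNA strand acting on other transcripts, but the siRNA sequence is not given in the labels. The joined word ATGCTCCA had a further effect of -0.034 (-0.083 to 0.015) over the leading word alone, which does not decide. The loss of LncND or an unrelated regulator of such UTRs stays open.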
